A study of Mus musculus with 2 samples.

How the data were processed

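H3K9ac chromatin immunoprecipitation was done on leukemic spleen cells of NUP98/HOXD13 mice with the human GFI1-36S or GFI1-36N cDNA, 1 library per genotype (2 libraries). Per the labels' protocols, spleens were homogenised, red cells were lysed, cells were fixed in formaldehyde at 0.4%, chromatin was sheared by sonication (20 min), and libraries were made with an NEBNext Ultra kit. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.0c, SAMtools and the mouse genome build mm10, without saying what each did. How regions were called, counted and annotated is not given in the sources used here. No input or spike-in control was used here. STAR is built for spliced RNA reads, and the settings with which it was run on these DNA fragments are not given in the sources used here.

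The authors' deposited table gives 1 log2 value per library for each of 20615 regions, a common set for both libraries. Regions were 300 to 18900 bp long (median 1350), all multiples of 150 bp, with no overlaps. The deposited log2 values were taken back to reads: 2 to the power of the value was a whole number in every region of the 36S library, apart from 13 regions that share a floor of 0.9 reads standing for 0. In the 36N library it was a whole multiple of 1.02, within 0.01 reads. So the 36N values had been multiplied by 1 constant, whose meaning is not given in the sources used here, and values were not divided by region length. The design written beforehand allowed for counts, log2 or linear values; the values being log2, differences of the deposited log2 values were used, with no pseudocount. Reads in regions numbered 4989632 (36S) and 3292869 (36N), a ratio of 0.672 after the constant. Total sequencing depth is not known. At the median of 95 and 83 reads per region, counting error alone gives a 95% half-width of 20.1% and 21.5%.

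The difference is 36N minus 36S in log2 units. Its 95% interval is the exact conditional (Clopper-Pearson) interval of the 2 read numbers and covers counting error only, not the spread between animals. Where 1 library had 0 reads, only the lower end of the interval is given, and no fold. A difference of 1 log2 unit (2-fold) or more was counted as higher or lower; this is a rule of size, not a test. The level-adjusted difference is the residual from a lowess trend of the difference on the mean level (fraction 0.3 of regions, fitted on autosomes). Each of 12553 gene symbols was given the region with the highest mean of the 2 libraries among those the table assigns to it, up to 49994 bp away. There were 10 symbols turned into dates, in 19 regions, which were left out. Of the symbols, 11791 (93.9%) matched RefSeq genes of GRCm38.p6. One predicted symbol, Gm20388, is assigned to 91 regions and hides genes beneath it, so a second assignment used the RefSeq genes that overlap a region by at least 1 bp.

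For each of 23 gene lists, the median difference was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean level. The percentile describes these libraries only, and some genes are in more than 1 list. Limits of 2.5 and 97.5 were set after the values were seen. The lists, the tests, the rule for named genes and the first alternatives were fixed before the data were examined. By that rule the text names, per direction, the 12 genes with the largest difference relative to the median region among genes at or above the median level of all genes. Clone and locus names (Gm with digits, Rik, LOC and the like), Olfr, Vmn, Mir, Snor, pseudogenes and sex-linked genes are left out of these 12. It also takes Gfi1 and Gfi1b, the 2 highest and 2 lowest members of each list at or above that level, all other members of the GFI1 target and HoxA lists, and the sex-linked genes. Some genes that the rule takes are not reported here. Outside it, Hoxb7, Hoxd3, Ctsg, F13a1, Ccr2, Spic, Ank1, Gata1, Tfrc, Add2, Gp1ba, Vwf, Mcm5, Ccnd3, Cdkn2b, Mx1, Ifit3, Themis, Cd3g, Hdc, Mecom, Kdm1a, Fas, Gapdh, Actb, Ywhaz, Polr2a, Gfap, Hoxa3, Hoxa4 and the Xist region were chosen after their values were seen. All further genes in the closing observations were chosen that way too.

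The alternatives were centring on the median region, the lowess trend, quantile normalization, scaling to active promoters, other sizes, level and length filters, autosomes only, and the mean over a gene's regions. RefSeq assignment and leaving out chromosomes 15, X, Y and MT were added after seeing the data. The procedure was tested on simulated data for 36N against 36S (20615 regions, 12553 genes, 200 of them changed). After adjustment for level it placed 100% of 4-fold and 64% of 2-fold changed genes past 1 log2 unit, and 0% of unchanged strong regions. The deposited difference was not scored in this way. Simulated reads had counting error only, with no spread between animals or precipitates. Of 2000 simulated intervals 96.2% covered the true value, a list lowered 2-fold came out at percentile 0, and 1.5% of 200 random lists fell outside the limits. Intervals of chromosome medians come from 2000 bootstrap resamples of regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.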

Results

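Acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in leukemic spleen cells. The mice expressed the NUP98/HOXD13 fusion, which drives myelodysplasia and leukemia, and carried a human cDNA of the transcriptional repressor GFI1. One genotype had the common form with serine at residue 36 (GFI1-36S), and the other had the variant with asparagine (GFI1-36N). The series title ties the 36N form to acute myeloid leukemia and to epigenetic therapy, and the comparison asks where H3K9ac differs between the genotypes. Each genotype had 1 library, so no difference below has a replicate check, and no p-value is given. The 95% intervals of single regions cover counting error in these libraries only, and the bootstrap intervals of medians cover the spread over regions only. The 36S library held 4989632 reads in 20615 regions (median 95 reads per region) and the 36N library 3292869 reads (median 83). Values across regions had a Pearson r of 0.90 and a Spearman rho of 0.91; both are across regions of the 2 libraries, and regions are not independent replicates.

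H3K9ac was lower in the 36N library at strong regions and slightly higher at weak ones. The median difference, 36N minus 36S on the log2 scale, was −0.40 over all regions (quartiles −0.81 and 0.22). In the weakest 10% of regions by mean level the median was 0.12, and in the strongest 10% it was −0.75 (SD over regions 0.28). By the size rule of 1 log2 unit, 1545 regions were higher in the 36N library and 2915 were lower. The counting interval excluded 0 at 1475 of the former and 2876 of the latter. This split rested on the scaling. Relative to the median region, 2964 regions were higher and 1054 lower, so that the higher regions made up 73.8% of those past the rule in place of 34.6%. After subtraction of the trend with level, 1673 were higher and 1711 lower, a share of 49.4%, and quantile normalization gave 49.7%. Scaling to active control promoters gave 5455 higher and 385 lower, a share of 93.4%. The values of single genes below are differences as deposited, unless a level-adjusted difference, the distance from the trend, is named. At strong regions, where the trend is near −0.75, a negative value as deposited can lie above the trend.

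**Figure D1:**
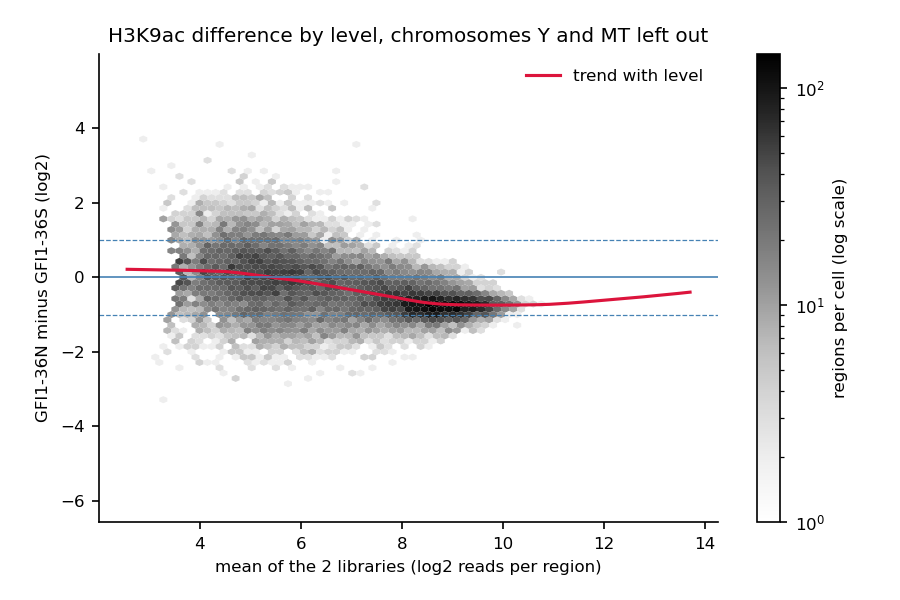
Difference between the libraries (y axis, GFI1-36N minus GFI1-36S, log2) against the mean of the 2 libraries (x axis, log2 reads per region), with regions binned in cells shaded by their number; dashed lines mark 1 log2 unit and the red line the trend. The median difference is 0.12 in the weakest 10% of regions and −0.75 in the strongest 10%.

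Known GFI1 target genes went both ways as deposited, and as a list they did not pass the limits in the main comparison. Of 33 listed genes, 23 had a region, and 17 of these lay above the trend (median level-adjusted difference 0.30). Granulocyte and monocyte genes, with which the list shares Elane, Cebpe, S100a9 and Csf1r, lay above the trend too (9 of 10 and 8 of 11), and erythroid genes lay below it (9 of 10). As deposited, 3 were higher by 1 log2 unit or more (Tlr4, Hoxa10 and Meis1, the last through a region 8093 bp downstream of the gene) and 3 were lower by as much. With genes assigned by RefSeq overlap, 2 were higher and 2 lower. After adjustment for level 3 were higher and 1, the region given to Myc, was lower. As deposited 13 of the 23 were negative, 12 with an interval below 0, and 10 were positive, 7 with an interval above 0. Tlr4, the receptor for bacterial lipopolysaccharide, had 36 reads in the 36S library and 148 in the 36N library (chromosome 4, 66827401 to 66829050, difference 2.07, interval 1.53 to 2.63). Csf1r, the receptor for macrophage colony-stimulating factor, differed by 0.66 (0.27 to 1.06) and its ligand gene Csf1 by 0.46 (0.18 to 0.75). Cebpa, a myeloid transcription factor, differed by 0.26 (0.10 to 0.42), and Elane, which encodes neutrophil elastase, by 0.68 (0.24 to 1.12). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was lower at −1.50 (−1.68 to −1.33), as was Egr1 at −1.04 (−1.27 to −0.82); their level-adjusted differences were −0.76 and −0.36. Il7r, the interleukin-7 receptor gene on chromosome 15, was at −0.94 (−1.70 to −0.22), Bax at −0.80 (−1.02 to −0.58), E2f5 at −0.66 (−1.0 to −0.34), Socs3 at −0.63 (−0.83 to −0.43) and Cebpe at −0.52 (−0.75 to −0.29). The region given to Myc, at −1.73, lies 47077 bp from that gene on chromosome 15 and overlaps Pvt1 in RefSeq. The list's median difference of −0.40 lay at percentile 88.45 of level-matched random lists, inside the limits used. With the trend subtracted the percentile was 98.98, and the 6 alternative settings ran from 98.77 to 99.92, all above the upper limit.

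The region assigned to Gfi1 itself had few reads in both libraries. It (chromosome 5, 107717701 to 107718450) held 28 reads in the 36S library and 32 in the 36N library, a difference of 0.22 with an interval of −0.56 to 1.0, so no difference was detectable at this depth. Reads on the mouse gene do not separate the human cDNA forms and so do not check the genotype labels. Gfi1b, the paralog of Gfi1, had no region among those analysed here.

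Hoxa10 and Hoxa13, of the HoxA cluster that sustains self-renewal in myeloid leukemia, carried more H3K9ac in the 36N library, while the call of the HoxA list as a whole depended on the setting. Hoxa10 (chromosome 6, 52233301 to 52235100) had 44 and 131 reads in the 36S and 36N libraries, a difference of 1.60 (1.10 to 2.13). Hoxa13 differed by 1.33 (0.43 to 2.30) on 15 and 37 reads. The interval of Hoxa11, −0.36 to 1.18, included 0. The Meis1 region, with 11 and 26 reads, lies 8093 bp downstream of the gene (1.27, 0.20 to 2.43), and a region that overlaps Meis1 in RefSeq, with 14 and 17 reads, was at 0.31 (−0.80 to 1.44). Pbx3, a Hox cofactor, was at −0.65 (−0.93 to −0.38), close to the trend at its level. Over the 6 of 14 genes with a region the median was 0.88, at percentile 97.80, just past the upper limit. In all 5 alternative settings run the percentile was inside the limits, from 93.99 to 97.48. The lowest came from assignment by RefSeq overlap, which measured 8 genes. One region then counted for both Hoxa3 and Hoxa4 was lower, at −1.02 (−1.29 to −0.76). Of the HoxB, HoxC and HoxD genes, 4 of 28 had a region (percentile 74.68), and of these 4 Hoxb7 alone passed 1 log2 unit, with 65 and 179 reads (1.49, 1.07 to 1.92). By RefSeq overlap 7 had a region (percentile 82.81), and Hoxd3 passed it as well, with 12 and 29 reads (1.30, 0.28 to 2.41).

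Most granulocyte and monocyte genes lay above the trend in the 36N library. Of 10 measured granulocyte genes 9 had a positive level-adjusted difference (median 0.31, percentile 98.02). By RefSeq overlap (97.46) and among members at or above the median level (95.80) the percentile was inside the limits. None passed 1 log2 unit as deposited, and the deposited median was −0.26, opposite in sign to the level-adjusted one. Csf3r, the receptor for granulocyte colony-stimulating factor, was higher by 0.32 (0.10 to 0.55) and Ctsg, which encodes cathepsin G, by 0.75 (0.46 to 1.04), while Ngp, a secondary granule gene, was at −0.58 (−0.75 to −0.41), 0.15 above the trend. The region given to Fcgr3, 1.18 above the trend, lies 14116 bp downstream of that gene. A region over Fcgr3 in RefSeq was 0.58 above the trend. The region given to Ly6g, the only member below the trend, lies 20943 bp downstream. Among monocyte and macrophage genes, 8 of 11 lay above the trend (median 0.57, percentile 95.36, inside the limits). The percentile was 99.18, past the upper limit, with the trend subtracted, and 95.91, inside the limits, by RefSeq overlap. The regions given to Ly6c2 and Ccr2, both above the trend, lie 20860 bp upstream and 20000 bp downstream of these genes. The region given to Cx3cr1, also above the trend, overlaps Csrnp1 in RefSeq. Klf4, a transcription factor of monocyte differentiation, had 194 and 451 reads (chromosome 4, 55529401 to 55532550, difference 1.24, 1.0 to 1.49). F13a1, coagulation factor XIII A of monocytes and platelets, had 117 and 249 reads (1.12, 0.79 to 1.45). Cd14, a surface receptor of monocytes, was at 0.04 (−0.23 to 0.31). Spic, a factor of red pulp macrophages, had only 15 and 10 reads in its region, which lies 23422 bp upstream.

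The listed erythroid genes carried much less H3K9ac in the 36N library. Of 10 measured genes 8 were lower by 1 log2 unit or more (6 relative to the median region, 7 after adjustment for level), none was higher by that much, and the list median was −1.72, below all 10000 level-matched random lists (percentile 0). Among the 8 is Tfrc, at −1.05, through a region 10170 bp downstream of the gene. The region given to Add2, at −0.97, lies 9696 bp upstream. By RefSeq overlap, which gave neither gene a region, 9 of 10 measured genes were lower by 1 log2 unit or more. Hba-a2, an alpha-globin gene, had 538 reads in the 36S library and 92 in the 36N library (chromosome 11, 32296951 to 32298600, difference −2.52, −2.86 to −2.20). The beta-globin region given as Hbb-b1, which overlaps Hbb-bs in RefSeq, had 724 and 126 reads (−2.5, −2.78 to −2.22). Gata1, the erythroid master regulator on the X chromosome, was at −2.17 (−2.55 to −1.81). Epor, the erythropoietin receptor gene, was at −1.76 (−2.01 to −1.52). Ank1, which encodes ankyrin, differed by 0.15 as deposited (−0.16 to 0.47) and alone lay above the trend, by 0.58. A further list of erythroid genes, drawn up after these values were seen but before its own were, had 17 measured genes with a level-adjusted median of −0.16 and a percentile of 14.9, inside the limits. Red cells were lysed before fixation, per the labels. Of 6 measured megakaryocyte genes, 5 lay below the trend (percentile 10.94), led by Gp1ba at −1.29 (−1.80 to −0.80) and Vwf at −1.12 (−1.43 to −0.82).

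Genes of the cell cycle lay slightly below the general trend in the 36N library. Of 24 measured genes 21 were below it, with a level-adjusted median of −0.22 (median difference −0.93, percentile 0.08). As deposited 10 were lower by 1 log2 unit or more and none was higher by that much, but only 2 were lower by as much relative to the median region and 1 after adjustment for level. Cdkn2a, which encodes the p16 and ARF tumor suppressors, had 620 and 168 reads (chromosome 4, 89293951 to 89296500, difference −1.86, −2.11 to −1.61). Cdc6, a replication licensing factor, was at −1.41 (−1.64 to −1.19), Mcm5 of the replicative helicase at −1.27 (−1.46 to −1.09), and Ccnd3, cyclin D3, at −1.26 (−1.51 to −1.02). Bub1, a mitotic checkpoint kinase gene, was at −0.65 (−0.93 to −0.37), and −0.12 from the trend. Because Cdkn2a and Cdkn2b restrain the cycle, the list does not describe proliferation alone. Small shifts below the trend were not limited to these genes. Level-adjusted medians were −0.24 for Hist (percentile 1.73), −0.19 for Polr (4.25) and −0.15 for Rpl genes (0.40), families chosen after seeing the data. Active promoter controls were at −0.09 (6.48), but at 0.04 by RefSeq overlap. Other families, such as Gtf at 0.01 and Map at 0.51, did not lie below the trend.

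Interferon-stimulated genes formed another lower group. Of 15 measured genes 7 were lower by 1 log2 unit or more and none was higher by that much, with a median of −0.93 at percentile 0.18. Relative to the median region 4 were lower and 1 higher, and after adjustment for level 3 were lower and none higher. The antiviral gene Rsad2 had 550 and 126 reads (chromosome 12, 26454301 to 26457000, difference −2.10, −2.39 to −1.82). Oasl2, of the oligoadenylate synthetase family, was at −1.81 (−2.06 to −1.55) and Bst2, tetherin, at −1.44 (−1.63 to −1.26). Mx1, at 0.70 (0.23 to 1.17), and Ifit3, at 0.49 (−0.11 to 1.10), stood on the other side. Irf1 was at −0.19 (−0.39 to 0.01).

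T cell genes did not pass the limits as a list, with 3 of 11 measured genes lower by 1 log2 unit or more. Themis, a T cell signalling gene, had 313 and 59 reads (−2.38, −2.81 to −1.98), Lck, the T cell kinase, was at −1.60 (−1.87 to −1.35) and Cd3g at −1.29 (−1.92 to −0.69). Over the list the percentile was 13.78. With genes assigned by RefSeq overlap the percentile was 0.37, and with the mean over all regions of a gene it was 0.76. Neither B cell genes (7 measured, percentile 41.91) nor NK cell genes (5 measured, percentile 85.13) passed the limits. Dendritic cell genes (9 measured) were at percentile 35.32, and mast cell and basophil genes (4 measured) at 6.67, with Hdc, histidine decarboxylase, at −1.83 (−2.22 to −1.44). Endothelial and stromal genes (5 measured) were at 69.10, none past 1 log2 unit.

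Stem and progenitor genes did not stand apart as a list (15 measured, median −0.43, percentile 33.12). By RefSeq overlap, with 14 measured, the median was 0.26 and the percentile 94.20, so the sign depended on the assignment. Mecom, a self-renewal factor that leukemias can overexpress, was the highest with 17 and 95 reads (2.51, 1.75 to 3.35). Kit differed by 0.17 (−0.09 to 0.44) and Sox4 by 0.35 (0.10 to 0.60). The region given to Ly6a was at −1.68 (−1.91 to −1.45), but it lies 4328 bp upstream on chromosome 15 and overlaps predicted genes in RefSeq. The genes of GFI1 corepressors and histone acetylation enzymes moved with the trend (21 measured, median −0.59, percentile 72.16). Hdac1 was at −0.94 (−1.13 to −0.74), the corepressor gene Rcor1 at −0.80 (−0.92 to −0.68) and Kdm1a, the lysine demethylase that GFI1 recruits, at −0.62 (−0.78 to −0.46). In apoptosis and p53 genes (15 measured, percentile 12.16), the antiapoptotic Bcl2 was higher by 0.90 (0.66 to 1.13) and the death receptor gene Fas by 0.98 (0.59 to 1.38), against lower values at Cdkn1a and at Trp53inp1 (−1.11, −1.29 to −0.94). As deposited 3 were lower by 1 log2 unit or more and none was higher, whereas after adjustment for level 2 were higher (Bcl2 and Fas) and none was lower. NF-kB and inflammatory genes (17 measured) were at percentile 92.72. Rel differed by 0.19 (0.01 to 0.38) and Icam1 by −1.33 (−1.60 to −1.07). With only the members at or above the median level, the percentile was 99.86 for NF-kB and inflammatory genes and 98.66 for corepressors and histone acetylation enzymes. Immediate early genes (12 measured) were at 86.08.

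**Figure D2:**
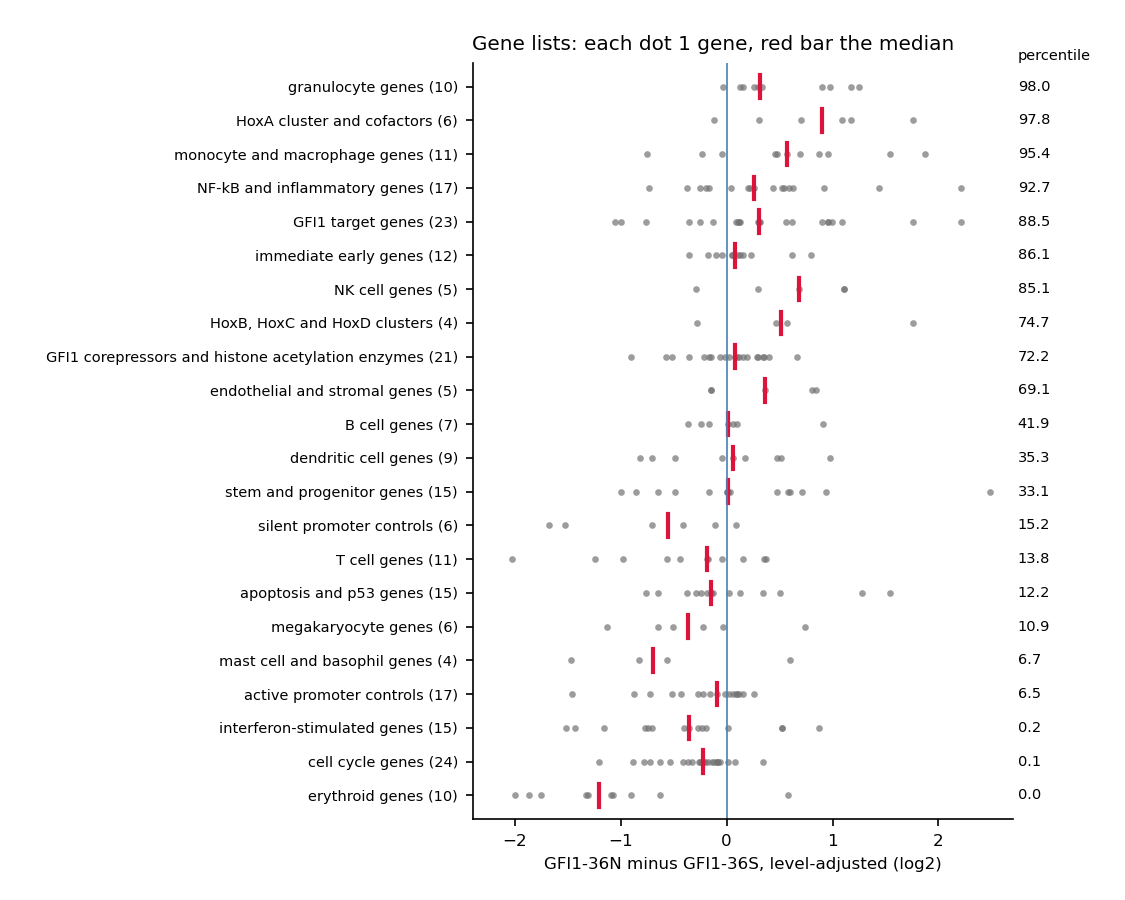
Level-adjusted difference of each measured gene (x axis, GFI1-36N minus GFI1-36S, log2) in 22 lists (rows, number measured in parentheses), with red bars at list medians and the percentile of the unadjusted median among level-matched random lists at the right. Erythroid, cell cycle and interferon-stimulated genes lie at percentiles 0, 0.08 and 0.18, and granulocyte and HoxA genes at 98.02 and 97.80, which came inside the limits in 2 and in all 5 of the alternative settings run for them, respectively.

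Among genes at or above the median level, the 12 lowest ranged from −3.55 to −2.14 and the 12 highest from 1.05 to 2.37. The 2 ends are not alike. Of the 5605 genes ranked, 841 were lower by 1 log2 unit or more as deposited, 14 were higher by as much, and 327 lay above 0. Igf2bp3, an oncofetal RNA-binding protein gene, was the lowest of all, with 944 reads in the 36S library and 79 in the 36N library, 11.7-fold higher in 36S (chromosome 6, 49213051 to 49216350, difference −3.55, −3.90 to −3.22). It was followed by the zinc transporter gene Slc39a4 at −2.53 (−2.83 to −2.24), the 2 globin regions, Tmcc2, Parp10, the interferon-inducible Rtp4, Tnfrsf13c (the BAFF receptor gene), Fam113b (Pced1b in RefSeq), Igfbp6, Fads2 and Chid1. Of these 12, 5 lay on chromosome 15, which held 3.89% of regions. Gphn, the gephyrin gene, was the highest, with 104 and 529 reads, 5.18-fold higher in 36N (chromosome 12, 78225451 to 78228000, difference 2.37, 2.07 to 2.69). H2-Q7, a nonclassical class I histocompatibility gene of a family of near-identical copies, was at 1.83 (1.53 to 2.14), so its value is uncertain. Atp11a was at 1.76 (1.46 to 2.07) and Prkce, protein kinase C epsilon, at 1.58 (1.33 to 1.83). Pura, Gnaq, Klf4, Sgpl1, Kif1b, Lrrk1 and Bbx completed the group together with a region given to Lilrb4, which lies 29288 bp upstream of that gene. Of the 102 named genes with a region, 49 passed 1 log2 unit. The rule takes many of them for the size of their difference, so this count does not describe genes in general. It includes the 4 measured sex-linked genes, which had no reads in the 36S library.

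The 2 samples differed in sex. The region over the Xist promoter (X chromosome, 103480651 to 103483200, given the symbol Tsix in the table) had 519 reads in the 36S library and 8 in the 36N library, 63.7-fold higher in 36S (difference −5.99, −7.21 to −5.0). On the Y chromosome 12 of 33 regions had no reads in the 36S library and 23 to 207 reads in the 36N library. Ddx3y had 207 reads, and the lower end of the interval of its difference was 5.82. Uty had 157 reads (lower end 5.42), Eif2s3y 81 (4.45) and Kdm5d 78 (4.39). The sex-linked list was at percentile 100, but its 4 measured genes all had no reads in the 36S library. The floor value fixed this percentile, so it adds no support. X-linked regions had a median level-adjusted difference of −0.41. Sex and genotype thus differed together, and no comparison here separates them.

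Chromosome 15 also stood apart along its whole length. Its 802 regions had a median difference of −0.86 and a level-adjusted median of −0.49, while the other 18 autosomes lay between −0.04 and 0.04 after adjustment. All 10 of its segments of 10 Mb with at least 20 regions were below 0, from −0.67 to −0.25. Among 226 such segments on the other autosomes, 1 was lower than the highest of chromosome 15. Weak regions of chromosome 15 had an adjusted median of −0.52 and strong regions −0.48.

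**Figure D3:**
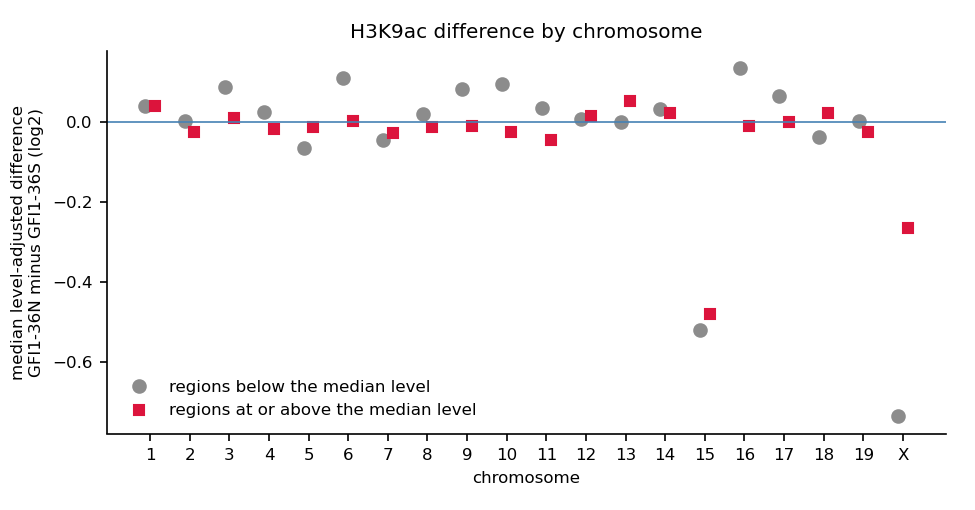
Median level-adjusted difference (y axis, GFI1-36N minus GFI1-36S, log2) of each autosome and of X (x axis), for regions below the median level (grey circles) and at or above it (red squares). Chromosome 15 lies at −0.52 and −0.48, the X chromosome at −0.74 and −0.27, and the other autosomes between −0.07 and 0.14.

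Most regions overlapped genes. By the table's own annotation 14910 regions (72.3%) overlapped a gene, 2412 lay downstream of one, 2221 upstream, and 1072 had no gene assigned. The median difference was −0.49 for overlapping regions, −0.18 for downstream and −0.16 for upstream regions and −0.04 for those with no gene. After adjustment for level these became 0.00, −0.11, −0.13 and −0.06. Of 20 housekeeping genes used as active promoter controls, 17 were assigned a region, which overlapped the gene for 14 by the table's annotation. All 17 set the scaling to active promoters. Their median was 9.30 in the 36S and 8.48 in the 36N library (median difference −0.82, percentile 6.48). By RefSeq overlap, with 14 genes, the median difference was −0.69 and the percentile 66.69. As deposited, Gapdh was at −0.58 (−0.75 to −0.41), which is 0.15 above the trend, and Rplp0 was at −1.15 (−1.35 to −0.95). Of 32 genes silent in blood cells 6 had a region, with medians of 6.78 and 5.99 (percentile 15.17). The gap between active and silent medians was 2.52 in the 36S and 2.5 in the 36N library. Some control regions were poor stand-ins. Those given to Actb, Ywhaz and Polr2a lay 13547, 42370 and 14747 bp from these genes, and the silent controls Cela1 (chromosome 15) and Gfap had 545 and 310 reads in the 36S library. The region given to Tbp, at −0.97, overlaps Pdcd2 in RefSeq, and a region over Tbp itself was at −0.50.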

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

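Regions 1 log2 unit or more higher and lower in the 36N library (1545 and 2915) numbered 2964 and 1054 when centred on the median region, and 5455 and 385 when scaled to active promoters. Lower regions numbered 1711 after subtraction of the trend and 1727 after quantile normalization. A size of 0.58 gave 3051 and 8351, and a size of 2 gave 302 and 241. At or above the median level there were 172 and 1639, with a median difference of −0.66, and among regions of the commonest length, 600 bp, 257 and 168. The last 2 start from fewer regions by construction. Autosomes alone stayed within 1.5 times of both counts. Centring on the median, the trend, quantiles and active promoters moved the median region by 0.40, 0.38, 0.37 and 0.82.

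GFI1 target genes (percentile 88.45) came to 98.98 with the trend, 98.97 with quantiles, 99.63 with the mean over regions, 99.13 among strong members, 98.77 by RefSeq and 99.92 without chromosomes 15, X, Y and MT. HoxA genes (97.80) came in the same order to 97.40, 97.48 and 94.74, then 93.99 by RefSeq and 97.33 without those chromosomes, all inside the limits. Granulocyte genes (98.02) came to 95.80 among strong members and 97.46 by RefSeq, and their median (−0.26) turned positive when centred (0.13), with the trend (0.31) and with quantiles (0.29). Monocyte genes (95.36) came to 99.18 with the trend, 99.15 with quantiles and 99.87 among strong members. They stayed inside the limits by RefSeq (95.91), with the mean over regions and without chromosomes 15, X, Y and MT. The strong members include the regions given to Cx3cr1 and Ly6c2, which do not overlap these genes in RefSeq. T cell genes came to 0.76 with the mean over regions and 0.37 by RefSeq. Among strong members corepressors and acetylation enzymes came to 98.66 and NF-kB genes to 99.86. The causes were not tested. Erythroid, cell cycle and interferon-stimulated genes stayed below 2.5 in all 6 settings run for lists. For the 49 named genes past 1 log2 unit, all 240 alternative values kept their sign, but fewer stayed past it: 43 centred, 38 with the trend, 40 with quantiles, 40 with the mean over regions, and 43 of 44 by RefSeq. For a gene with 1 region, such as Hba-a2, Tlr4 or Hoxa10, the mean over regions is the main value by construction. RefSeq overlap gave these genes the same region again. Such genes therefore add no check in these 2 settings. The kept signs also say little about centring and the trend. Centring moved each value by 0.40 and the trend by less than 1 log2 unit, too little to reverse a sign. With the trend all 20 higher genes stayed past 1 log2 unit and 18 of 29 lower ones. The 20 include the 4 measured sex-linked genes, whose 36S value is the floor. Where the trend is negative, subtracting it can only raise a higher gene. RefSeq assignment and the left-out chromosomes were chosen after seeing the data.

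Not run were a pseudocount (the values are log2), the region nearest the gene start (no strand in the annotation used), values per kilobase and leaving out a library (1 per genotype). Values per kilobase leave the difference of a region as it is but change its mean level. The weak and strong groups, the trend, the level matching and the region chosen per gene could then differ. Median length was 450 bp in the weakest 10% of regions and 3150 bp in the strongest 10%. Counting intervals are widest at weak regions. The SD of the difference over regions was 1.10 in the weakest 10% and 0.28 in the strongest 10%; how much of this is depth was not tested.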

Other observations

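The tests below were chosen after the patterns were seen, except the check on further erythroid genes, whose list and bound were written before its values were seen. In 59 families of genes that share a symbol stem (15 or more genes each, chosen after seeing the data), genes with Map symbols lay highest. Most encode kinases of the MAP kinase pathways, but Map1lc3a and Map6d1 encode microtubule-associated proteins. All 10000 level-matched random lists had a lower median than the 22 genes (percentile 100), and 19 of them lay above the trend (level-adjusted median 0.51, against −0.07 as deposited). Map4k3, with 76 and 292 reads, differed by 1.97 (1.60 to 2.35), Map3k9 by 1.07 (0.75 to 1.38) and Map3k10 by 0.51 (0.27 to 0.75), whereas Map3k6 was at −1.47 (−1.72 to −1.23). Sorting nexin genes (Snx, 26 genes, percentile 99.65) had 18 members above the trend, among them Snx24 at 1.04 (0.63 to 1.46) and Snx20 at 0.15 (−0.07 to 0.36). Zinc finger genes with Zfp symbols (306 genes) were at percentile 99.72. Ribosomal protein genes of the large subunit (Rpl, 39 genes, 4 on chromosome 15) were at 0.40, while those of the small subunit (Rps, 34 genes) were inside the limits at 10.9. Further families outside the limits were translation initiation factors (Eif, 44 genes, 6 on chromosome 15) at 0.13, histone genes (Hist, 16 genes) at 1.73, solute carriers (Slc, 197 genes) at 98.59 and Phf genes (15 genes, 3 on chromosome 15) at 98.38. The level-adjusted median of the Phf genes was nonetheless −0.10, below the trend. In all, 8 of 59 families lay outside the limits, and with 59 families some do so by chance.

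RefSeq assignment recovered further genes that the table's symbols hide, chosen after their values were seen. Alas2, the erythroid heme synthesis gene on the X chromosome, had 351 and 56 reads (−2.62, −3.06 to −2.21). Epb42, of the red cell membrane skeleton, was at −1.86 (−2.15 to −1.59), and the interferon-stimulated Ifit1 at −1.96 (−2.27 to −1.65). Spi1, which encodes the myeloid factor PU.1, was at −0.16 (−0.31 to −0.02), above the trend by 0.58. On chromosome 5, from 14900101 to 15716250, all 27 regions were below the trend (median −1.12), with 1529 and 763 reads in total. These are neighbouring regions, not 27 separate observations. They lie in the lowest 10 Mb segment of the autosomes other than 15 (10 to 20 Mb, 41 regions, −0.66). That segment alone was lower than the highest of chromosome 15. Outside the sex chromosomes, 1 region had no reads in the 36S library, in Clmn on chromosome 12 (104864551 to 104865000), with 38 reads in the 36N library.

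A change limited to regions at or above the median level would leave weak regions of chromosome 15 near those of other autosomes (−0.07 to 0.14). The median of its weak regions was −0.52 (bootstrap interval −0.63 to −0.45), and weak minus strong was −0.041 (−0.17 to 0.06). Weak regions can also lie over genes, as at Il7r, so this split by level does not exclude a change at promoters. The trend with level cannot account for the low values, since the median of −0.49 (−0.54 to −0.45) is what remained after its removal. A difference in the number of copies of chromosome 15 between the samples may be the source, as a hypothesis. For 2 copies against 3 in all cells the value would be −0.58, inside the interval of the weak regions but outside that of all regions. These intervals resample regions of 1 pair of libraries, so they do not decide for or against that ratio. Segments of 10 Mb ran from −0.67 to −0.25. A ratio cannot tell a gain in 36S from a loss in part of the 36N cells, and no karyotype or input DNA was analysed here. On X, where copies differ with sex, weak regions were at −0.74 (−0.83 to −0.65) and strong ones at −0.27 (−0.30 to −0.21).

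The decline of the difference with level cannot come from a single scale factor, which would move all regions alike: the median of the strongest 10% of regions minus that of the weakest 10% was −0.87 (−0.92 to −0.85). How regions were called and counted is not given, so an effect of depth beyond such a factor is not excluded. Less enrichment over background in the 36N precipitate is a possible explanation that these values do not decide. Scaled reads in regions were 0.672 of those in the 36S library, but with total depth unknown this ratio does not separate enrichment from depth. The gap between active and silent controls, 2.52 and 2.5, decides nothing either, since it rests on 6 silent genes that include Cela1 and Gfap, both low in 36N. Lower acetylation at strong promoters in the 36N cells stays open as well; these cannot be told apart with 1 library per genotype and no input or spike-in used here.

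The low erythroid genes did not follow from their level, since the list was at percentile 0 of level-matched lists. Fewer erythroid cells in the 36N sample could lower all such genes. As a check, 43 further erythroid symbols gave 17 measured genes. Of these 12 lay below the trend and 6 were lower by 1 log2 unit or more, among them Rhd (454 and 143 reads) and Dyrk3 (235 and 69), but their median was at percentile 14.9, short of the bound of 2.5, so the check left this open. An effect of GFI1 genotype within erythroid cells cannot be told apart from it, since 1 library per genotype gives no sample in which the share of erythroid cells is equal; sex and red cell lysis also stay open.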
